A study of Micropterus salmoides with 20 samples.

How the data were processed

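RNA from the hypothalamus of largemouth bass was measured on 20 one-colour Agilent oligonucleotide arrays, with 4 arrays in each of 5 groups. The groups were control females, control males, females fed dieldrin, males fed dieldrin, and males fed dieldrin together with E2. Groups and replicate numbers came from the sample titles. For 2 control arrays the title and the gender label disagree on the sex, so that the title of one says male and its gender label female, and the reverse for the other. They were grouped by title, and every comparison with controls was repeated with the gender label and without both arrays. The labels do not say that replicates are separate fish, so p-values measure the spread between these samples, which may in part be technical.

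The intensity columns were deposited by the authors as scanner output of Agilent Feature Extraction 10.1.1.1, per the file headers, with spatial detrending and multiplicative detrending switched on for the processed signal. The flag columns, of other units, mark outlier spots, saturated spots and spots well above background, per the file headers. The authors also deposited a table of log2 values that its first line describes as quantile normalized. Each of its 20 columns correlated best with the array of the same name, at 0.9958 or more across probes. Its column medians lay between 7.628 and 7.631. It was used only as an alternative source of values.

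Each array held 15744 spots, of which 536 were control spots and 15208 were probes of 60 bases. The main values were log2 of the processed signal minus the log2 of each array's 75th percentile over the probes. A level below is in log2 units relative to that percentile. Outlier spots were left out and saturated spots kept, although no probe was saturated. A probe was tested where it was well above background on at least 4 of the 20 arrays, which kept 14182 probes and left out 1026. Of all probes, 10288 were well above background on all 20 arrays and 544 on none. Between 11458 and 14018 probes per array were well above background, and the 75th percentile of the signal ranged from 494.8 to 1337 intensity units. The number of arrays limits the precision.

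All 20 arrays entered one limma 3.58.1 fit in R 4.3.3 (lmFit, contrasts.fit and eBayes), and a probe was called at a Benjamini-Hochberg adjusted p under 0.05 within its contrast. Adjusted p-values below are from this fit. On data simulated with the residual spread of the real probes, but with probes drawn independently, no probe was called without a change in any of the 7 contrasts. The real probes are correlated across arrays, so the simulation does not give the false calls of the real data. Of 100 probes changed by 2 log2 units among 14182, the fit recovered 74% for dieldrin in females, 68% for dieldrin in males, 52% for the sex difference, 74% for dieldrin and E2 against control, 76% for E2 added to dieldrin, 70% for sex on the control diet and 76% for sex on dieldrin. Of 100 changed by 1 log2 unit it recovered 36%, 48%, 20%, 37%, 39%, 42% and 40% in the same order, and with both kinds present it also called 2 to 9 unchanged probes per contrast.

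Where a probe was not well above background on any array of a group, its fold is a bound. The bound sets the brighter group's mean against the dimmer group's mean of, per array, the higher of the probe's own level and the lowest level among probes well above background. No fold is given where that bound is under 1.

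The files do not pair probes with genes. Their description column reads unknown for every probe, and none of the 29 sequence accessions among the probe names was in the RefSeq gene table of assembly ASM1485139v1. The rule fixed before the data were examined named the probes with the largest changes among those called whose arrays do not overlap between the groups, and those with the smallest p where fewer than 10 passed. It was written for probes with a gene name. It was applied to probe IDs instead, with at most 2 that were higher and 2 that were lower per comparison. The 27 gene lists fixed before the data were examined could not be matched to any probe, so no gene list was tested. The files give the probes no genome position.

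The arrays lay on 3 slides, called slide 1, slide 2 and slide 3, which were scanned separately on the same day. Slide 1 held all 8 arrays of fish fed dieldrin alone. Slide 2 held the 4 arrays of males fed dieldrin and E2 and 4 control arrays, and slide 3 held the other 4 control arrays. Dieldrin alone and slide 1 therefore cannot be told apart. Each sex difference, and dieldrin with E2 against control, can be estimated within slides.

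Alternatives fixed before the data were examined were quantile normalization, normexp background correction with an offset of 50, the authors' table, 2 other filters on dim probes, slide as a random or fixed term, a replicate block, only the groups compared, the 2 treatments of the conflicting labels, and each array of a comparison left out. Others were chosen after seeing the data. They were array weights, single slides, control female 4 left out of comparisons that do not include it, a repaired normexp correction and the removal of spots in shifted areas of an array. The repair was needed because 11 spots of dieldrin male 3 and 4 spots of dieldrin E2 male 2 had a background reading over 10 times the array's median, up to 381044 against 52. With those spots included, the normexp values of these arrays correlated with the main values at 0.6551 and 0.8108, and at 0.9503 and 0.9632 without them. The array of control female 4 had 577 non-uniform spots and a dim stripe covering 1380 tested probes, in which the median deviation of the surrounding 9 by 9 spots was under -0.5 log2 units. The most such probes on any other array was 822.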

Results

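Expression in the hypothalamus was compared between largemouth bass on a control diet and on diets with dieldrin, an organochlorine pesticide, at 3 mg/kg. A further group of males received dieldrin at 3 mg/kg with E2, an estrogen, at 0.7 mg/kg. Each of the 5 groups had 4 arrays, and 14182 probes were tested on each. Because the files do not pair probes with genes, results are given for probe IDs and their 60-base sequences.

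In females, more probes were called higher than lower with dieldrin. Of 14182 probes, 322 were higher and 11 lower in dieldrin-fed than in control females at an adjusted p under 0.05 (limma). The mean log2 difference of the higher probes was 1.80. The balance depended on the setting, since array weights gave 1171 higher and 637 lower, leaving out dieldrin female 1 gave 611 and 211, and of 2156 probes at an unadjusted p under 0.05, 1312 were higher. The probe UF_Msa_CF_120209 (sequence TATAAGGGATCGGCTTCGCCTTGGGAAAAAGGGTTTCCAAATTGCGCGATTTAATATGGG) had a level of -3.86 ± 0.57 (SD, n = 4) in dieldrin-fed females. It was not well above background on any control female array, so dieldrin-fed females were at least 3.78-fold higher, with an adjusted p of 0.0453 from limma. It was not called with quantile normalization (adjusted p of 0.0524 from limma) or with the authors' table (0.0635). Control males 2 and 4, at -3.63 and -3.87, lay near the level of dieldrin-fed females, while control males 1 and 3 were at -6.99 and -7.51. With the repaired normexp correction its log2 difference was 0.59, and it was not called. That correction adds an offset of 50, which shrinks the differences of dim probes by construction. The 0.59 therefore cannot be set against the bound. The probe UF_Msa_CF_124250 was at -2.58 ± 0.11 (SD, n = 4) with dieldrin and at -5.87 ± 0.47 (SD, n = 4) without, but only 1 of the 4 control female arrays measured it well above background, and the log2 difference of 3.29 ± 0.72 (SE) became 1.32 with the repaired normexp correction, where it was not called. Among the lower probes, UF_Msa_CF_123256 (sequence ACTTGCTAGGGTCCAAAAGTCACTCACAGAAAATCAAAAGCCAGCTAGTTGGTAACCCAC) was at -5.78 ± 0.88 (SD, n = 4) with dieldrin and -4.09 ± 0.16 (SD, n = 4) without, but only 1 of the 4 dieldrin-fed female arrays measured it well above background. Its log2 difference of -1.69 became -0.67 with the repaired normexp correction, and it was not called there. UF_Msa_CF_118660 was not well above background on any array of dieldrin-fed females and on 1 array of control females, so no fold is given. All control females were on slides 2 and 3 and all dieldrin-fed females on slide 1, so diet and slide cannot be told apart here. The count changed when any single array was left out. It was 1 without dieldrin female 3, without dieldrin female 4 or without control female 3, 2 without dieldrin female 2 or control female 4, 27 without control female 1, 45 without control female 2, and 822 without dieldrin female 1. Across these fits, the probes at an unadjusted p under 0.05 varied less, from 1475 to 2656. With normexp as planned 0 probes were called, and with the repaired normexp correction 9. Without both arrays of conflicting sex labels 20 were called. UF_Msa_CF_118660 was among them, while UF_Msa_CF_120209, UF_Msa_CF_124250 and UF_Msa_CF_123256 were not. Over the alternative settings that tested it, the call of UF_Msa_CF_120209 was lost in 13 and kept in 8. For UF_Msa_CF_124250 these were 10 and 11, for UF_Msa_CF_123256 14 and 7, and for UF_Msa_CF_118660 7 and 14.

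**Figure D1:**
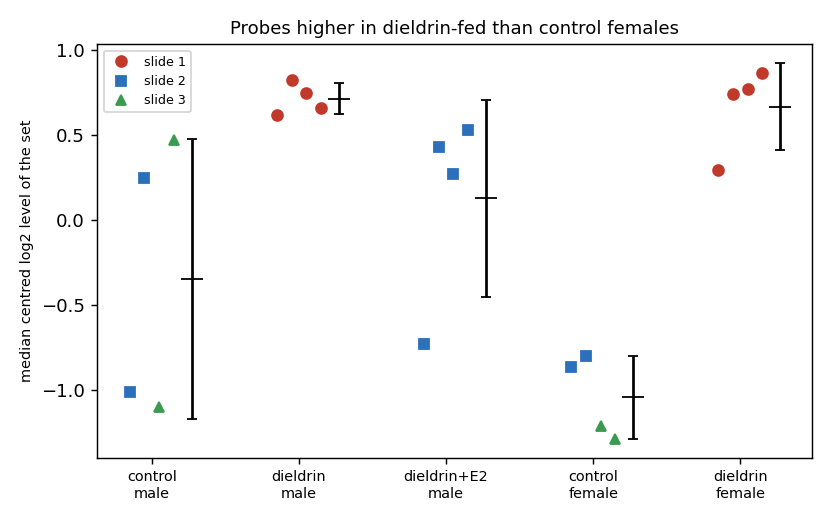
Median centred log2 level (vertical axis, log2 units) of the 322 probes higher in dieldrin-fed than control females, for each of the 20 arrays by group, coloured by slide, with the mean and SD of each group. Control males 2 and 4 lie at 0.25 and 0.47, above the other control males at -1.01 and -1.10.

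In males, 12 probes were higher and 1 was lower in the dieldrin-fed than in the control group (limma, adjusted p under 0.05). Without both arrays of conflicting sex labels 7 were higher and 8 lower, and without control male 3 there were 8 and 5, so the balance rested on few arrays. In the main fit 9 of the 12 were also among the 322 of females, where 0.273 would be expected of independent lists. These comparisons contrast different arrays, but they share the slides and each probe's estimate of the spread, so the lists are not independent. The probe UF_Msa_AF_106793 (sequence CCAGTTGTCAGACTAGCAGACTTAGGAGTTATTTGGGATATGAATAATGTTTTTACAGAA) was at -0.57 ± 0.25 (SD, n = 4) in dieldrin-fed males and -2.74 ± 0.36 (SD, n = 4) in control males, a 4.47-fold difference with an adjusted p of 0.000105 from limma. UF_Msa_CF_121751 was 3.69-fold higher, at -1.63 ± 0.18 (SD, n = 4) against -3.51 ± 0.41 (SD, n = 4). The lower probe, UF_Msa_AF_102623, was well above background on all 4 control male arrays and on none with dieldrin, and its bound gives no fold. Under normexp as planned and repaired its log2 difference reversed to 1.02 and 0.30. Across all tested probes, the log2 differences of females and males correlated at 0.462. Probes are not independent replicates. Diet and slide cannot be told apart in males either. The count was 112 without control male 4, 8 without control male 2, 5 without dieldrin male 1, 2 or 3, and 3 without dieldrin male 4. It was 0 when only the 8 arrays compared entered the fit, 0 with normexp as planned and 52 with the repaired normexp correction. Under normexp as planned UF_Msa_AF_106793 and UF_Msa_CF_121751 had log2 differences of 2.02 and 1.73, with adjusted p-values of 0.315 and 0.371 from limma.

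No probe passed the test of the difference between the sexes in their response to dieldrin. The limma interaction called 0 probes, with 521 at an unadjusted p under 0.05. With slide as a fixed term, which the design allows for this contrast, it again called 0 probes, with 547 unadjusted. The 322 probes were chosen by the comparison of females. They had a mean log2 difference of 1.80 in females and 1.11 in males. Their mean interaction was 0.69, and their mean difference between control females and control males was -0.72. That choice favours a larger difference in females, so these means test nothing. The smallest p belonged to UF_Msa_AF_102623, with an adjusted p of 0.285 from limma. Of the 4 groups compared, only control males had it well above background on any array, so no size is given, and its interaction reversed to -1.12 and -0.41 under normexp as planned and repaired. Without dieldrin female 1, 1 probe was called.

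No probe passed between males fed dieldrin and E2 and control males. limma called 0 probes, with 610 at an unadjusted p under 0.05. The probe UF_Msa_AF_103633 (sequence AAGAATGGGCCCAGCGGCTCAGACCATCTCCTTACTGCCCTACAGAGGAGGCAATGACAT) had a level of -4.12 ± 1.21 (SD, n = 4) with dieldrin and E2. In control males it was at 2.83 ± 3.04 (SD, n = 4), a log2 difference of -6.96 ± 1.20 (SE) with an adjusted p of 0.201 from limma. It passed without control male 3 (adjusted p of 0.00504 from limma), without both arrays of conflicting sex labels (0.00574) and without dieldrin E2 male 4 (0.0449). Control males 1 to 4 were at 5.35, 1.65, -0.92 and 5.25, so leaving out control male 3 took away the lowest of them. The same probe differed from control males by -6.03 ± 1.20 (SE) with dieldrin alone and by -4.76 ± 1.20 (SE) in control females. For E2 added to dieldrin the difference was -0.93 ± 1.20 (SE). None of these differences passed. The probe is one of the 9 described among the other observations. UF_Msa_CF_124665 was at -3.06 ± 0.31 (SD, n = 4) against -4.15 ± 0.29 (SD, n = 4), with an adjusted p of 0.268 from limma. For dieldrin alone this probe was called in females (log2 difference of 1.55, adjusted p of 0.0167 from limma) and in males (1.25, 0.0395). With E2 added to dieldrin it differed by -0.16 ± 0.23 (SE), which did not pass. Both differences from control males share those arrays. With slide as a fixed term limma called 0 probes, with 646 unadjusted, and within slide 2 alone, with 4 arrays against 2, it called 3. The count was 16 without dieldrin E2 male 4, 9 without control male 3, and 1 without control male 2. Without both arrays of conflicting sex labels it was 9, all lower.

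Adding E2 to dieldrin was accompanied by lower levels of 4 probes and higher levels of none, relative to males fed dieldrin alone (limma, adjusted p under 0.05). The balance depended on the setting. There were 15 higher and 41 lower with slide as a random block, and 2 and 21 with array weights. Quantile normalization gave 1 and 6, and leaving out dieldrin male 3 gave 1 and 2. UF_Msa_AF_106793 was at -2.89 ± 0.21 (SD, n = 4) with E2 and -0.57 ± 0.25 (SD, n = 4) without, 4.96-fold lower with an adjusted p of 3.75e-05 from limma. UF_Msa_CF_121751 was 4.56-fold lower, at -3.82 ± 0.44 (SD, n = 4), a log2 difference of -2.19 that became -1.37 with the repaired normexp correction, and it was not called when only the 8 arrays compared entered the fit (adjusted p of 0.0819 from limma). Under normexp as planned neither probe was called, at log2 differences of -1.60 and -1.17. Relative to control males, the log2 differences of these probes with dieldrin and E2 were -0.15 ± 0.21 (SE) and -0.30 ± 0.26 (SE), which did not pass. The males fed dieldrin alone were on slide 1 and those fed both on slide 2, so E2 and slide cannot be told apart. This comparison shares the dieldrin-fed males with that of dieldrin against control. Their log2 differences correlated at -0.668 across probes, where unchanged groups give -0.50, and the covariance was -0.208 against -0.0934. With different dieldrin-fed males in each comparison the correlation was -0.185. The count was 2 without dieldrin male 1, 2 or 4 and without dieldrin E2 male 2.

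**Figure D2:**
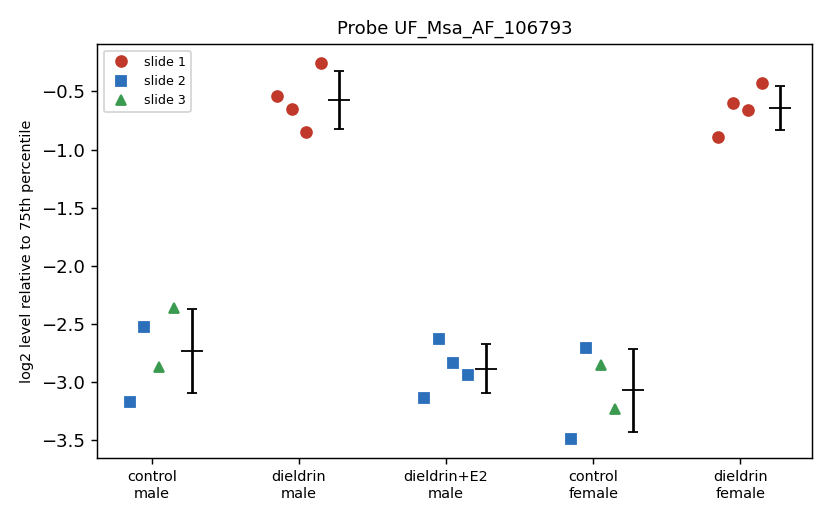
Level of probe UF_Msa_AF_106793 (vertical axis, log2 units relative to the 75th percentile of the array) for each of the 20 arrays by group, coloured by slide, with the mean and SD of each group. The group means are -0.57 and -0.64 for males and females fed dieldrin alone, all on slide 1, and -2.89 for males fed dieldrin and E2, -2.74 for control males and -3.07 for control females.

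On the control diet, 1 probe was lower in females than in males and none was higher (limma, adjusted p under 0.05). UF_Msa_AF_102623 (sequence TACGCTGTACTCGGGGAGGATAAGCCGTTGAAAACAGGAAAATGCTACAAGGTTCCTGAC) was at -5.42 ± 0.63 (SD, n = 4) in control males and not well above background on any control female array, so males were at least 1.29-fold higher, with an adjusted p of 0.0317 from limma. Under both normexp corrections its log2 difference was 0.040, towards females, and it was not called. With slide as a fixed term 1 probe was called. Within slide 2 and within slide 3, with 2 arrays against 2, limma called 0 probes, with 249 and 432 at an unadjusted p under 0.05. The call was lost when the gender label set the group. It was also lost without control female 1, 2, 3 or 4 and without control male 1, 2 or 4, while 4 probes were called without control male 3.

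On the dieldrin diet, females and males did not differ in any probe that passed. limma called 0 probes, with 267 at an unadjusted p under 0.05, and all 8 arrays were on slide 1. UF_Msa_CF_124221 was at -4.71 ± 0.52 (SD, n = 4) in females and -3.17 ± 0.76 (SD, n = 4) in males, with an adjusted p of 0.792 from limma. Without dieldrin female 1, 1 probe was called.

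**Figure D3:**
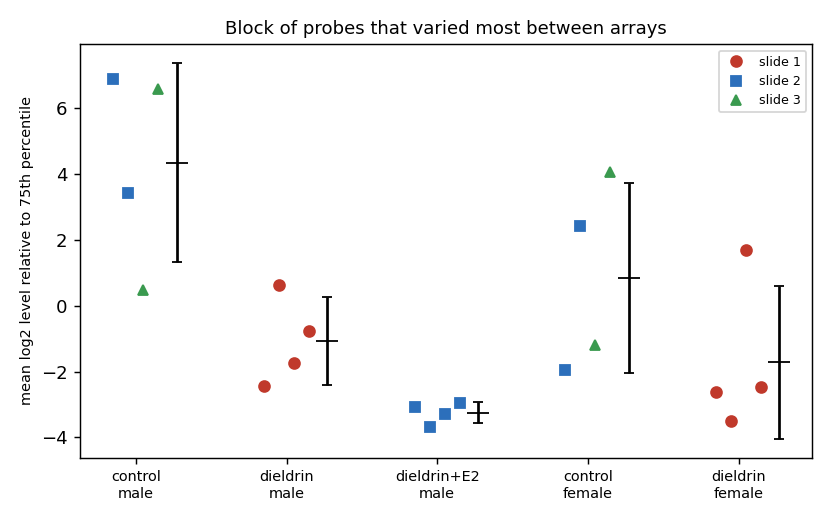
Mean level (vertical axis, log2 units relative to the 75th percentile of the array) of the 9 probes described among the other observations, for each of the 20 arrays by group, coloured by slide, with the mean and SD of each group. The 9 were chosen from 18 probes that varied widely between arrays, because they moved together. Control males range from 0.47 to 6.91 and males fed dieldrin and E2 from -3.68 to -2.95.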

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

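Tests of the slide, of GC content, of variation among fish, of the dim stripe and of the diets, and the simulations, were chosen only after the result was seen.

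Among 100 groups of 4 arrays examined, 4 held an array far from the others, and chance gives about 1 in 20. The array of control female 4 had 577 non-uniform spots, where the other control females had 4 to 16. Dieldrin female 2 had 51, where the others had 8 to 14. Probe UF_Msa_CF_124250 was at -5.86 on the array of dieldrin E2 male 1, where the others were at -2.94 to -2.72. Probe UF_Msa_CF_121751 was at -3.65 in control female 1, where the others were at -3.08 to -3.00.

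The probes higher in dieldrin-fed than control females are the main pattern to weigh. Of 35 splits of the 8 arrays, 1 gave as many as 333 calls, the real one, and the highest other gave 1. Being the highest of 35 is the most this test can show, so chance is made less likely but is not excluded. The test cannot separate diet from slide. The probes of this pattern had a median GC content of 51.67%, against 45% for the tested probes (means of 50.18% and 47.65%). Each array's GC trend does not account for most of their difference. Without that trend 0.931 of the median log2 difference was left (1.76 before, 1.64 after). A shift linked to GC content in only some probes was not tested, so it is not excluded. The dim stripe of control female 4 does not account for most of the calls either, since 0.907 of them were left without it. The male arrays entered the choice of these probes through the filter and the shared estimate of the spread, but not through the female difference. They are therefore not a fully independent check. In males, the set was higher with dieldrin on all 4 arrays (exact two-sided permutation p = 0.0286, the smallest possible). That difference follows slide as well as diet. Control males 2 and 4 lay far above the other control males. Males fed dieldrin and E2 ranged from -0.73 to 0.53 and overlapped control males (exact two-sided permutation p = 0.257). The set thus also varied within a diet, and variation that ignores the diet is not excluded. Slide 1 and dieldrin cannot be told apart, because no array of a fish fed dieldrin alone lay on another slide. The change of males fed dieldrin and E2 on slide 2 was a median of 0.463 of that of males fed dieldrin alone. Both changes use the same control males, and 20 simulated sets of unchanged probes gave 0.371 to 0.602, so nothing is read from this ratio.

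The probes called in dieldrin-fed against control males were weighed too. Of 35 splits, 1 gave as many as 13 calls, the real one, and the highest other gave 0. With only 35 splits this makes chance less likely but does not exclude it. Males fed dieldrin and E2, on slide 2, showed a median of 0.301 of the change. The control males are shared here as well. The ratio lay below the 0.333 to 0.739 of simulated sets of unchanged, independent probes. But an effect of slide 1 and an effect that E2 reverses both lower it, so it does not separate them. Of 10 spike-in levels, 2 differed between slide 1 and the other slides at a permutation p under 0.05. An effect of slide 1 and an effect of dieldrin that E2 reverses cannot be told apart, because the dieldrin-only arrays were all on slide 1.

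In 2 other comparisons, splits other than the real one gave as many calls. For E2 added to dieldrin 4 of 35 splits gave at least 4 calls, with a highest other of 19. For sex on the control diet 4 of 35 gave at least 1 call, with a highest other of 7. Where the real split called 0 probes, every split gives at least as many and the count tests nothing. These were the sex difference (100 of 100 drawn splits, highest other 14), sex on dieldrin (35 of 35 splits, highest other 140) and dieldrin with E2 against control (35 of 35 splits, highest other 2865). The 2865 calls point to a structure of the samples that does not follow the groups.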

How the results depend on the processing

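Array weights, single slides, control female 4 left out of comparisons without control females, the removal of shifted areas and the repaired normexp correction were chosen after seeing the data. The sex difference of the dieldrin response kept 0 calls under every alternative except leaving out an array (0 to 1). Calls for dieldrin in females went from 333 to 208 with the authors' table, 221 with probes well above background on all arrays, 759 with slide as a random block, 614 with only the groups compared, 527 with the gender label, 20 without both conflicting arrays, 1808 with array weights, 205 without shifted areas on all arrays and 1 to 822 without an array. Calls for dieldrin in males went from 13 to 31 with probes well above background on all arrays, 67 with the random block, 0 with only the groups compared, 885 with array weights, 22 and 23 without shifted areas on 1 and on all arrays, 3 to 112 without an array of the comparison and 22 without control female 4. For E2 added to dieldrin the 4 calls became 7 with quantile normalization, 7 with probes well above background on all arrays, 56 with the random block, 1 with only the groups compared, 23 with array weights, 10 and 10 without shifted areas, 2 to 5 without an array of the comparison and 10 without control female 4, which only enters the shared spread. For dieldrin with E2 against control the 0 calls became 1 with only the groups compared, 9 without both conflicting arrays, 1 with array weights, 3 within slide 2, 1 without shifted areas on all arrays and 0 to 16 without an array. For sex on the control diet the 1 call became 0 with quantile normalization, the authors' table, probes well above background on all arrays, only the groups compared, the gender label, array weights, slide 2 alone, slide 3 alone and shifted areas left out on 1 array, 2 without both conflicting arrays, and 0 to 4 without an array. For sex on dieldrin the 0 calls became 3 with array weights and 0 to 1 without an array. The cause was not tested, except that fewer arrays or probes enter some settings. The consensus correlation within slides was -0.0748, so the random block narrows the errors between slides and does not correct for slide.

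Normexp as planned called 0 probes for dieldrin in females, 0 in males, 0 for E2 added to dieldrin and 0 for sex on the control diet. Corrupt background readings spoiled the correction of 2 arrays. Repaired, it called 9 for dieldrin in females, 52 in males, 4 for E2 added to dieldrin and 0 for sex on the control diet. The corrupt readings therefore do not account for the loss of most calls in females or of the call for sex on the control diet. Both normexp versions add an offset of 50 before log2, which by construction shrinks the log2 differences of dim probes. How much of the loss the offset accounts for was not tested. UF_Msa_AF_102623 reversed under both, to 1.02 and 0.30 for dieldrin in males, to -1.12 and -0.41 for the sex difference and to 0.040 and 0.040 for sex on the control diet. UF_Msa_CF_118925 reversed for sex on dieldrin, to -0.75 and -0.059. The cause was not tested.

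Same-numbered arrays of different groups shared only a number. Their deviations from the group means correlated at 0.020 on average, over 0.1 in 11 of 40 pairs, and 4 of 20 arrays correlated best with their own number. A replicate block gave 557 calls for dieldrin in females, 5 in males, 2 for E2 added to dieldrin and 0 for sex on the control diet, and changed no other count. The alternative settings for gene lists were not run, because no probe could be matched to a gene.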

Other observations

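The test of the diets was chosen only after the result was seen, and so were the block of probes below and the simulation of independent probes. Of the tested probes, 18 varied by over 6 log2 units between arrays, without the highest and lowest array. The block is the 9 of these, counting the widest, that correlated above 0.8 with the widest. Within groups the median correlation of the 9 was 0.713. Their mean level was 4.34 ± 3.03 (SD, n = 4) in control males and 0.84 ± 2.88 (SD, n = 4) in control females. It was -1.07 ± 1.33 (SD, n = 4) in males fed dieldrin, -1.72 ± 2.33 (SD, n = 4) in females fed dieldrin and -3.25 ± 0.31 (SD, n = 4) in males fed dieldrin and E2. Among them, UF_Msa_AF_106967 had a log2 difference of -10.6 and UF_Msa_AD_200185 one of -10.3 between males fed both compounds and control males, each with an adjusted p of 0.201 from limma.

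A candidate explanation for the block is the diet of dieldrin and E2, since all 4 males fed both lay below all 4 control males (exact two-sided permutation p = 0.0286, the smallest possible). The same test gave 0.0571 for dieldrin in males, 0.171 for dieldrin in females and 0.143 for sex on the control diet, limma called none of the 9 in the main fit, and the block was chosen for its spread over these same arrays. Without control male 3, UF_Msa_AF_103633 of the block passed for dieldrin and E2 against control (adjusted p of 0.00504 from limma). Control male 3 had the lowest block level of the control males. Diet does not account for the spread within a diet, from 0.47 to 6.91 in control males and from -1.96 to 4.08 in control females. Another is a varying amount of another tissue in the dissected piece. The bound set beforehand against it was met, as 2 probes outside the block followed it within groups against a median of 92 for 100 random probes. That bound was wrong, because simulated independent probes had a median of 1, so the 92 reflects structure shared by the arrays, and because the count leaves out the block's own members by construction. It was judged wrong only after the count was seen. The 2 followers also did not reach the 488.4 that would have spoken for tissue. How many transcripts a trace of tissue would bring was not tested, and no gene names are at hand to look for them. The sequences of the 9 probes were not translated or searched for what they encode. Tissue and other variation between samples were therefore not told apart.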
